A study of Arabidopsis thaliana with 4 samples.

How the data were processed

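RNA was measured in 4 libraries from whole Arabidopsis seedlings, 2 of wild type and 2 of atino80-5. Total RNA was selected for polyA and made into stranded libraries by a dUTP method, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, HISAT2, SAMtools, featureCounts, DESeq2 and deepTools without versions, and the TAIR10 genome. The annotation release, the strand setting of the counting and any filter on genes are not given in the sources used here. The genotype and the replicate number came from the labels, which do not say what the number marks.

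The authors deposited FPKM values for 23174 genes in each library, with the mean of each genotype, and a table of their DESeq2 test with the mean normalised signal over the libraries, a log2 fold change with its standard error, a test score, a p-value and an adjusted p. The fold changes and adjusted p-values were equal in both tables for all 23174 genes. The FPKM values are scaled by size factors, from the values themselves: combined with the mean normalised signal they gave whole reads for 100% of the 92696 values within a tolerance of 0.01. The gene length they imply was whole for 100% of genes and had a median ratio of 1.19 to the exon length of the reference annotation. For INO80 it was 8398 against 5305 bases and for FLC 5952 against 1180 bases, so introns were counted in the length and the FPKM of intron-rich genes is understated. This does not change the ratio of 1 gene's FPKM between libraries. It does shrink the difference in log2(FPKM + 1) that was tested, and can take such a gene below the minimum level of 1 FPKM. The size factors were 0.9995, 1.3479, 0.7849 and 0.9574, for wild type replicates 1 and 2 and atino80-5 replicates 1 and 2. The smallest total over the libraries was 2 reads. The wild-type libraries differed by a chi-square per degree of freedom of 13.0 and the mutant libraries by 40.6, so neither pair held the same library.

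Genes with a mean of at least 1 FPKM over the 4 libraries were tested (17642 genes). The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05. Log2 differences are therefore on the log2(FPKM + 1) scale, which understates the change of low genes, and folds in the text are ratios of mean FPKM. The adjusted p-values rest on spread shared between genes, since an exact permutation of 2 against 2 libraries cannot give a two-sided p under 0.33. Of the called genes, 8 had fewer than 10 reads in every library. Gene lists were tested two-sided with limma's camera at its preset correlation of 0.01 over lists with at least 3 tested members, with an estimated correlation and fry beside it. With an estimated correlation, camera rests on the few degrees of freedom that 4 libraries leave. A list can then hardly pass after adjustment, so a miss there says little about that list. Fry's directional p asks whether a list's genes move one way on balance and does not compare them with other genes. The same code was tested on simulated reads, drawn with an assumed spread between replicates, for 17663 genes in 2 against 2 libraries. Of genes changed 4-fold, 48 of 48 lowered and 50 of 50 raised were called. Of genes changed 2-fold, 20 of 50 lowered and 26 of 50 raised were called. Of 17465 unchanged genes 24 were called, a larger share of all simulated calls than the adjusted p threshold of 0.05 aims at.

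The 21 lists were written from general knowledge before the data were examined, with root and seed markers to watch the make-up of whole seedlings. Of their 278 genes, 267 had a name that matched the reference annotation (TAIR10.1), 11 did not and were left out, and 4 of the matched genes were not analysed here. That reference was used for names, chromosomes, exon lengths and overlaps, and no coordinates from it are given because its build may differ from that of the files. The genes named are INO80, the 10 largest rises and 10 largest falls with a gene symbol among called genes whose libraries did not overlap between genotypes, and up to 4 called members of each list, or 2 members where none was called. The rule for these was set before the data were examined. Other genes in the text, among them members below the minimum level, SESA2, FER1 and the genes named in the closing section, were named after their values were seen.

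For genes with no read in a genotype, the fold is a lower bound against 3 reads over the group. With 1 to 3 reads the ratio has an exact (Clopper-Pearson) 95% interval. Alternatives were other pseudocounts (0.1 and 5), no filter or a minimum of 5 FPKM, quantile normalisation, median centring, limma without trend or robust, the replicate number as a block, and each library left out. Added after seeing the data were limma voom on the recovered reads, removal of each library's trend against gene length, and scaling to total reads. DESeq2 and edgeR were not run. No locus of the chloroplast or mitochondrial genome was analysed here, so the planned share of organelle-encoded values is not given. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.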

Results

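Messenger RNA was measured by stranded, polyA-selected RNA-seq in whole Arabidopsis thaliana seedlings that were 14 days old. The seedlings had grown on plates in long days of 16 h light and 8 h dark at 22 °C. Wild type was set against atino80-5, a mutant of INO80, the ATPase of the INO80 chromatin remodelling complex, which slides nucleosomes and exchanges their histones. There were 2 libraries of each genotype and no other group. Expression of 23174 genes was given as FPKM, and whole reads could be recovered for every value. The libraries held 13846046 and 18406709 reads in wild type and 13068214 and 14746250 reads in atino80-5. Across genes, log2 values correlated at r = 0.9896 between the wild-type libraries and at r = 0.9732 between the mutant libraries. Correlations between genotypes lay between 0.9334 and 0.9679, the lowest for atino80-5 replicate 1, and genes are not independent replicates. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

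INO80 itself (AT3G57300, chromosome 3) was still transcribed in the mutant. Its level was 4.28 and 4.54 FPKM in the wild-type libraries and 2.72 and 3.13 FPKM in the atino80-5 libraries, from 535, 765, 267 and 375 reads. Both mutant libraries lay below both wild-type libraries, but the difference did not pass the test (log2 difference -0.46, SE 0.15, limma adjusted p = 0.117). Among the alternatives INO80 passed only with atino80-5 replicate 2 left out (log2 difference -0.54), a fit with 1 mutant library. Its limma adjusted p was 0.0673 with voom, 0.0551 with total-read scaling and 0.24 with the length trend removed. The authors' deposited table gave INO80 a log2 fold change of -0.59 with an adjusted p of 0.0967. The gene overlaps AT3G57290, and the values do not show which part of the gene the reads came from.

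The comparison asked which genes differ in expression between atino80-5 and wild-type seedlings in long days. All 5 tested seed and embryo markers, among them 2 cruciferin and 2 oleosin genes, rose in atino80-5 from near 0, and 8 of 10 tested genes of the iron deficiency list fell. The 5 seed markers, of 11 with values, reached the minimum level for testing only through their mutant values. The seed and iron lists both passed camera with its preset correlation, and neither did with an estimated one (adjusted p = 0.377 for each). With an estimated correlation 0 of 20 lists passed, since 4 libraries leave few degrees of freedom. The estimates themselves were 0.056 for seed and -0.0043 for iron, against the preset 0.01. The floral repressor gene FLC rose 6.02-fold, from 0.551 ± 0.0610 to 3.32 ± 1.14 FPKM (SD, n = 2). Jasmonate, phosphate-starvation and pathogenesis-related genes were among those that rose, and 3 UDP-glycosyltransferase genes were among the 10 largest falls of genes with a symbol. Of 17642 genes with a mean of at least 1 FPKM, 955 changed in the limma test at an adjusted p under 0.05, 528 of them raised and 427 lowered. Before adjustment, 4761 genes had a p under 0.05. Leaving out wild type replicate 1 or replicate 2 left 443 or 587 changed genes, and leaving out atino80-5 replicate 1 or replicate 2 gave 1561 or 6896. With libraries scaled to total reads the median difference of all genes moved from 0.03 to -0.157 on the log2 scale, and the calls split into 482 raised and 1151 lowered.

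Seed genes led the largest rises. CRA1, which encodes a cruciferin, a storage protein of the seed, stood at 0.390 ± 0.0790 FPKM in wild type and 25.0 ± 5.28 FPKM in atino80-5 (SD, n = 2). SESA5, which encodes an albumin of the seed, had no read in either wild-type library and 144 and 149 reads in the mutant libraries. Against a floor of 3 reads over the wild-type group, its rise had a lower bound of about 132-fold. LEA18, a late embryogenesis abundant gene, rose from 1.11 ± 0.0152 to 20.6 ± 2.04 FPKM. ICL, the isocitrate lyase of the glyoxylate cycle, rose from 2.07 ± 0.473 to 22.2 ± 1.18 FPKM. The phosphate-starvation RNA gene IPS1 rose from 3.10 ± 0.352 to 28.0 ± 5.94 FPKM, and PHI-1 rose from 3.98 ± 0.0930 to 33.8 ± 0.897 FPKM. The touch-induced calmodulin-like gene TCH2 stood at 357.5 and 152.4 FPKM in the mutant libraries against 36.1 and 34.0 FPKM in wild type. SADHU3-2, annotated as a pseudogene, rose from 0.298 ± 0.209 to 8.45 ± 2.52 FPKM. CRC and JAZ7 complete the 10 largest rises of called genes with a symbol and are described with their groups. All 10 had limma adjusted p-values between 0.00172 and 0.0169.

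Of the 10 largest falls among called genes with a symbol, 3 were in UDP-glycosyltransferase genes. UGT74E2, which glycosylates the auxin indole-3-butyric acid, fell from 101.5 ± 22.4 to 12.1 ± 3.35 FPKM (SD, n = 2). UGT74F2, a salicylic acid glucosyltransferase, fell from 198.0 ± 41.4 to 32.3 ± 10.8 FPKM, and UGT76E12 fell from 6.19 ± 1.09 to 0.589 ± 0.261 FPKM. The calmodulin-like gene CML37 fell 31.9-fold, from 93 and 139 reads to 4 and 1 reads. ELI3-2 fell 8.66-fold, PMZ 9.25-fold, SIB1 5.17-fold and the cytochrome P450 gene CYP81D11 5.03-fold. The defensin gene PDF1.2b fell from 29.5 ± 0.374 to 5.16 ± 0.687 FPKM, and BHLH100 is described with the iron genes. The limma adjusted p-values of these 10 genes ran from 0.00254 to 0.0173. TCH2, UGT74F2, CYP81D11 and UGT76E12 overlap a neighbouring gene, and reads of such a pair cannot be told apart where the strand setting of the counting is unknown.

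Genes of the iron deficiency response fell together. Of the 10 members of that list with a matched name, 8 fell, none rose and 2, OPT3 and FER1, did not pass. FIT had values but was left out because its name did not match the reference. The 4 related transcription factor genes BHLH38, BHLH39, BHLH100 and BHLH101, which are induced in plants short of iron, fell most. BHLH100 went from 11.4 ± 1.07 to 1.24 ± 0.246 FPKM (SD, n = 2) and BHLH38 from 3.33 ± 0.311 to 0.333 ± 0.00570 FPKM. BHLH39 fell 5.69-fold and BHLH101 4.82-fold. The other 4 that fell, named here after their values were seen, were the iron transporter gene IRT1 (3.23-fold), the ferric reductase gene FRO2 (3.14-fold), NAS4 (2.60-fold) and BTS (2.14-fold). Without wild type replicate 1 NAS4 and BTS had adjusted p-values of 0.0571 and 0.0868, and BTS had 0.124 without wild type replicate 2. FER1, which encodes the iron-storage protein ferritin and is induced by iron excess, stood at 118 ± 8.10 FPKM in wild type and 216 ± 25.8 FPKM in atino80-5 (limma adjusted p = 0.0592). Adjusted over the list alone, 8 members fell and FER1 rose. The list passed camera with its preset correlation (adjusted p = 9.94e-08, median log2 difference -1.45) and fry (adjusted p = 0.00856), with adjusted p = 0.377 with an estimated correlation. FER1, BHLH38 and BHLH101 overlap a neighbouring gene. Of the 14 root markers, none was called by limma, 4 had an unadjusted p under 0.05 and 1 was called, as higher, in the authors' deposited table. Their median log2 difference was -0.21, with PYK10 at 348 ± 34.3 and 551 ± 71.6 FPKM and NRT2.1 at 2.16 ± 0.0504 and 0.988 ± 0.399 FPKM in wild type and atino80-5 (camera adjusted p = 0.19 for the list). NRT2.1 was called lower with the replicate block (0.0385), with total-read scaling (0.0347) and without atino80-5 replicate 1 or replicate 2 (0.0206, 0.0473). PYK10, which overlaps a neighbouring gene, was called higher without atino80-5 replicate 1 (0.0472).

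**Figure D1:**
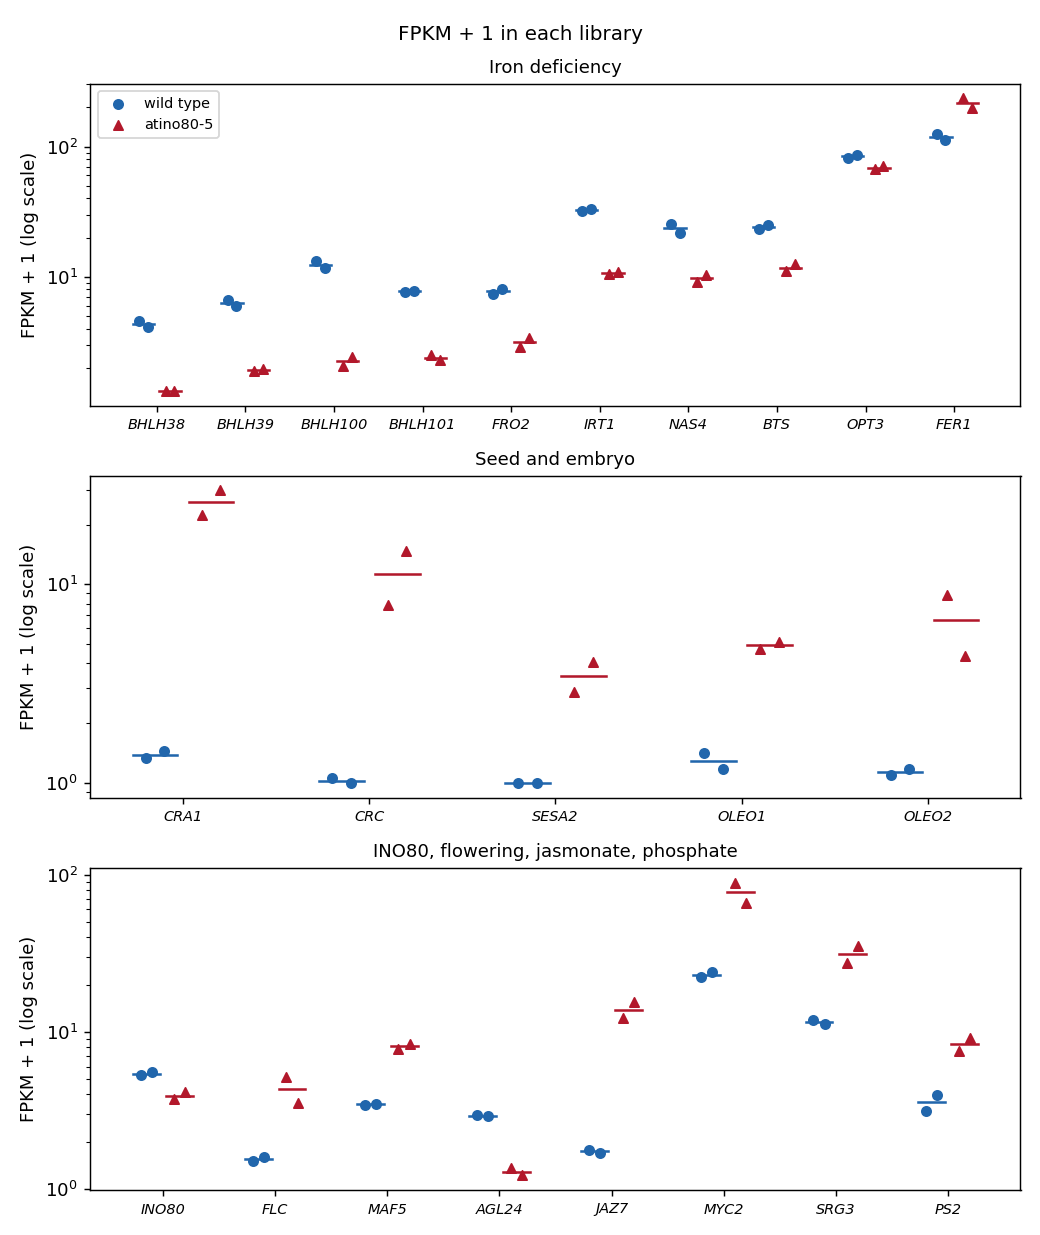
FPKM + 1 on a log axis in each library, with wild type as circles, atino80-5 as triangles and a line at the mean of the 2 libraries. All tested members of the iron deficiency and seed lists are drawn, with 8 other genes. Both mutant libraries lie below both wild-type libraries for the 8 iron genes that fell, and all 5 seed genes lie near 1, which is an FPKM of 0, in wild type.

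Of the 11 seed and embryo markers with values, 5 reached the minimum level and all 5 rose, also when adjusted over the list alone. Near 0 in wild type, they reached that level only through their values in atino80-5, so the count of 5 of 5 is set in part by the filter. Below it, SESA1, SESA3, SESA4 and ABI3 had no wild-type read and 27, 8, 5 and 19 reads in atino80-5, FUS3 had 7 reads in wild type and 3 in atino80-5, and LEC2 had 2 in each; these 6 are named after their values were seen. CRC, another cruciferin gene, had 2 and 0 reads in wild type and 180 and 440 reads in atino80-5, a ratio of 418 after scaling with an exact 95% counting interval of 115 to 3456. OLEO1 and OLEO2 encode oleosins, which coat oil bodies. OLEO1 rose from 0.292 ± 0.167 to 3.94 ± 0.303 FPKM and OLEO2 from 0.138 ± 0.0583 to 5.60 ± 3.14 FPKM (SD, n = 2). SESA2, also named after its values were seen, had no wild-type read, and its rise had a lower bound of about 21.6-fold. The median log2 difference was 2.45 on the scale of the test and 5.22 as a ratio of scaled reads with the floor in place for genes under 3 reads. With 5 members the list passed camera (adjusted p = 5.93e-07) and fry (adjusted p = 0.0139), with adjusted p = 0.377 with an estimated correlation. With no filter, camera at the preset correlation gave the list of 11 an adjusted p of 2.41e-07 and a median log2 difference of 1.29, and an estimated correlation was not run on those 11. Counting intervals and floors cover counting error only. OLEO1 and OLEO2 overlap a neighbouring gene.

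Among the flowering genes, the repressors FLC and MAF5 rose and the promoter AGL24 fell. Of the 7 genes on the FLC clade list, which also holds the repressor gene SVP, 2 rose and 5 did not pass. The numbers were the same adjusted over the list alone. MAF5 went from 2.47 ± 0.0205 to 7.08 ± 0.404 FPKM (SD, n = 2, limma adjusted p = 0.00847). FLC had an adjusted p of 0.0177, and an annotated gene, AT5G01675, overlaps it. The list with FLC and SVP did not pass camera (adjusted p = 0.182). With the gene-length trend of each library removed, an alternative chosen after seeing the data, its camera adjusted p was 0.0448. AGL24, a MADS-box gene that promotes flowering, fell 6.63-fold, from 1.94 ± 0.0157 to 0.292 ± 0.0935 FPKM, and was the 1 called member of 7 on the flowering promotion list. Adjusted over the list alone, 4 members fell. That list passed camera (adjusted p = 0.0215, median log2 difference -0.50), with adjusted p = 0.522 with an estimated correlation and 0.112 in fry. Its adjusted p was 0.0905 without wild type replicate 1, 0.0545 without atino80-5 replicate 1 and 0.0781 without atino80-5 replicate 2. SEP3, a floral organ identity gene, rose from 0.637 ± 0.101 to 3.10 ± 0.604 FPKM and was the only member of its list above the minimum level, too few for a list test there. With no filter the list of 8 had a camera adjusted p of 0.0853, and with voom on the recovered reads, an alternative chosen after seeing the data, 4 members gave 0.0123.

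Hormone and stress groups moved in part and in both directions. Of 16 jasmonate genes, 5 rose, 1 fell and 10 did not pass, with the same split adjusted over the list alone. JAZ7, a repressor of jasmonate signalling, rose 17.3-fold and MYC2, a transcription factor of that pathway, rose 3.47-fold. The synthesis genes AOC1 and AOS rose 2.30-fold and 2.22-fold. The other call upward was JAZ10, and the wound-response gene VSP1 fell, both named after their values were seen. MYC2 and JAZ10 overlap a neighbouring gene. Of 12 salicylic acid defence genes, 3 rose, 1 fell and 8 did not pass, and adjusted over the list alone 3 rose and 2 fell. PR1, a pathogenesis-related gene, rose from 0.318 ± 0.200 to 5.91 ± 0.398 FPKM (SD, n = 2), PR2 rose 2.17-fold and WRKY18 2.04-fold, while the camalexin gene PAD3 fell 2.60-fold. Of 14 cold and ABA genes, 3 rose and 1 fell, and adjusted over the list alone 4 rose and 3 fell. CBF1 and CBF2, near-identical cold regulators whose reads may be shared, rose 5.42-fold and 4.55-fold and KIN1 2.26-fold, while COR15A fell 2.31-fold. Of 9 senescence genes, WRKY53 rose and SAG13 fell 6.02-fold, with the same split adjusted over the list alone. None of these lists passed camera, with adjusted p-values of 0.157 for jasmonate (0.0424 without wild type replicate 2 and 0.0488 scaled to total reads), 0.19 for salicylic acid and 0.472 for each of the cold and senescence lists. Without wild type replicate 1 or replicate 2 the calls of AOS (0.182, 0.136), WRKY18 (0.139, 0.197), PR2 (0.0883, 0.236), COR15A (0.182, 0.0585) and WRKY53 (0.083, 0.0509) ended, as their adjusted p-values in that order show. AOC1 lost its call without wild type replicate 1 (0.121), and PAD3 (0.109) and KIN1 (0.22) without wild type replicate 2. With no filter on low values the adjusted p-values of PAD3, WRKY18, PR2 and KIN1 were 0.0642, 0.0596, 0.0712 and 0.0505, and that of VSP1 was 0.0565. WRKY18, PR2 and JAZ10 also lost their calls with the length trend removed (0.0551, 0.0769, 0.0577) and with total-read scaling (0.0569, 0.0608, 0.0542), and PR2 had 0.05 in limma without trend. Without wild type replicate 1 or replicate 2 JAZ10 had 0.258 and 0.144 and VSP1 0.254 and 0.0986. WRKY53 overlaps a neighbouring gene.

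Some phosphate-starvation genes rose, and clock genes went both ways. Of 10 phosphate-starvation genes, 4 rose and 6 did not pass, and adjusted over the list alone 5 rose. SRG3 went from 10.6 ± 0.508 to 30.1 ± 5.45 FPKM (SD, n = 2), the phosphatase gene PS2 rose 2.86-fold, the phosphate transporter gene PHT1;4 1.98-fold and the acid phosphatase gene PAP17 1.82-fold. The list passed camera (adjusted p = 0.000461, median log2 difference 0.50), with adjusted p = 0.522 with an estimated correlation and 0.103 in fry, and 0.061 in camera without atino80-5 replicate 2. Of 16 clock genes, 2 rose, 3 fell and 11 did not pass, and adjusted over the list alone 3 rose and 6 fell. The authors' deposited table called 3 of the 19 clock genes with values and a matched name higher and 7 lower. Below the minimum level, and named after their values were seen, LHY was 3.12-fold lower and PRR9 3.91-fold lower. Their DESeq2 adjusted p-values in the authors' table were 0.0114 and 0.0471. RVE8, also below that level, was 1.68-fold lower and not called there (0.516). The morning gene CCA1 fell 4.09-fold, PRR7 1.92-fold and LNK2 1.98-fold, while BOA rose 2.68-fold. RVE1, named after its values were seen, also rose. The sample details used here give no hour of harvest, and each library holds 1 time point. A shift in the timing of clock genes therefore cannot be told from a change in their level. The clock list did not pass camera (adjusted p = 0.19), and had adjusted p = 0.0425 after quantile normalisation and 0.0492 with voom. Without wild type replicate 1 or replicate 2 the adjusted p-values were 0.24 and 0.176 for PRR7, 0.16 and 0.162 for LNK2, 0.274 and 0.0942 for PHT1;4, and 0.367 and 0.178 for PAP17. Without wild type replicate 1 they were 0.106 for BOA and 0.0733 for PS2, and with no filter on low values 0.0729 for BOA, 0.064 for PRR7, 0.0659 for PAP17 and 0.0561 for RVE1. RVE1 had 0.126 and 0.227 without wild type replicate 1 or replicate 2. With the length trend removed BOA, PRR7 and PAP17 had 0.0577, 0.0577 and 0.0829, and with total-read scaling PHT1;4, PAP17 and RVE1 had 0.0507, 0.0852 and 0.0507. BOA had 0.0551 with a pseudocount of 5, and PRR7 and PAP17 had 0.0512 and 0.0504 with one of 0.1. PAP17 also had 0.0503 with quantile normalisation, 0.0511 with median centring and 0.0515 without trend. SRG3, PAP17, LNK2, BOA and RVE1 overlap a neighbouring gene.

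Genes of chromatin complexes, photosynthesis and cell division gave few or no calls. With a matched name, none of 4 INO80 complex genes and none of 8 SWR1 and H2A.Z genes was called by limma. Of them, 1 and 3 had an unadjusted p under 0.05. RVB2A, RVB2B, EEN, SWC4 and SWC6 had values but were left out because their names did not match the reference. The H2A.Z gene HTA9 stood at 83.2 ± 12.4 and 160 ± 49.5 FPKM (SD, n = 2) in wild type and atino80-5 (limma adjusted p = 0.103), and was the 1 member of these lists called in the authors' deposited table. HTA11 stood at 8.62 ± 2.16 and 14.1 ± 5.72 FPKM and ARP4 at 8.33 ± 1.04 and 10.5 ± 0.396 FPKM. GMI1 rose 3.71-fold and was the 1 call among 10 DNA damage genes, of which 2 rose adjusted over the list alone; its adjusted p was 0.0927 and 0.0582 without wild type replicate 1 or replicate 2. None of 19 light harvesting and Rubisco genes was called by limma, with 1 at an unadjusted p under 0.05 and 2 higher and 1 lower in the authors' deposited table. LHCB3 stood at 2839 ± 483 and 1753 ± 547 FPKM, and LHCB1.1, whose near-identical copies make it uncertain, at 2006 ± 224 and 3363 ± 1188 FPKM. None of 12 flavonoid, 12 DNA replication, 10 auxin and shade, 8 heat shock and 9 glucosinolate genes was called by limma, with 1, 5, 0, 0 and 3 at an unadjusted p under 0.05 in that order. The authors' deposited table called 1, 0, 0, 0 and 1 of their members with a matched name. Adjusted over each list alone, 2 glucosinolate genes fell and none of the other lists without a call had one. Those 2 were MYB28, at 49.3 ± 0.736 and 28.4 ± 2.64 FPKM, and CYP79F2, at 9.24 ± 0.507 and 5.52 ± 0.545 FPKM. MYB28 lay at an adjusted p of 0.051 over all genes and CYP79F2 at 0.0627. MYB28 passed without trend (0.0442), with median centring (0.0469), the replicate block (0.0458) and the length trend removed (0.042). Quantile normalisation, voom, total-read scaling and the replicate block gave CYP79F2 0.0478, 0.0454, 0.0269 and 0.0451, and the first 3 gave MYB28 0.0197, 0.0244 and 0.0192. Without atino80-5 replicate 1 or replicate 2 MYB28 had adjusted p-values of 0.0273 and 0.00442, and CYP79F2 had 0.00766 without atino80-5 replicate 2. Among members above the minimum level, the largest differences in the other lists were those of FLS1 at 32.3 ± 5.09 and 56.5 ± 22.7 FPKM, CHS at 166 ± 14.2 and 258 ± 86.6, CDT1A at 4.05 ± 0.943 and 2.05 ± 0.756, MCM3 at 4.95 ± 0.360 and 3.01 ± 0.321, SAUR19 at 1.2 ± 0.172 and 2.69 ± 1.66, PIF4 at 37.1 ± 1.04 and 26.1 ± 9.91, MBF1C at 5.76 ± 1.66 and 9.29 ± 4.16, and HSP90.1 at 3.38 ± 0.355 and 4.05 ± 0.364 FPKM. Without atino80-5 replicate 2, where 6896 genes were called, HTA9, HTA11, LHCB3, LHCB1.1, FLS1, CHS, CDT1A, MCM3, SAUR19, PIF4 and MBF1C were called with adjusted p-values from 0.00331 to 0.0212. CDT1A was also called with the replicate block (0.021) and MCM3 with total-read scaling (0.0382). HTA9, GMI1, LHCB3, CHS and MBF1C overlap a neighbouring gene. Below the minimum level, and named after its values were seen, the heat shock gene HSP17.6II had 12 and 20 reads in wild type and 1 and 0 reads in atino80-5, 23.8-fold lower after scaling with an exact 95% counting interval of 3.97 to 967. No list in this paragraph passed camera, with adjusted p-values from 0.0857 to 0.956, and fry gave DNA replication an adjusted p of 0.00766. After quantile normalisation the adjusted p of camera was 0.0194 for DNA damage and 0.0364 for glucosinolate synthesis.

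**Figure D2:**
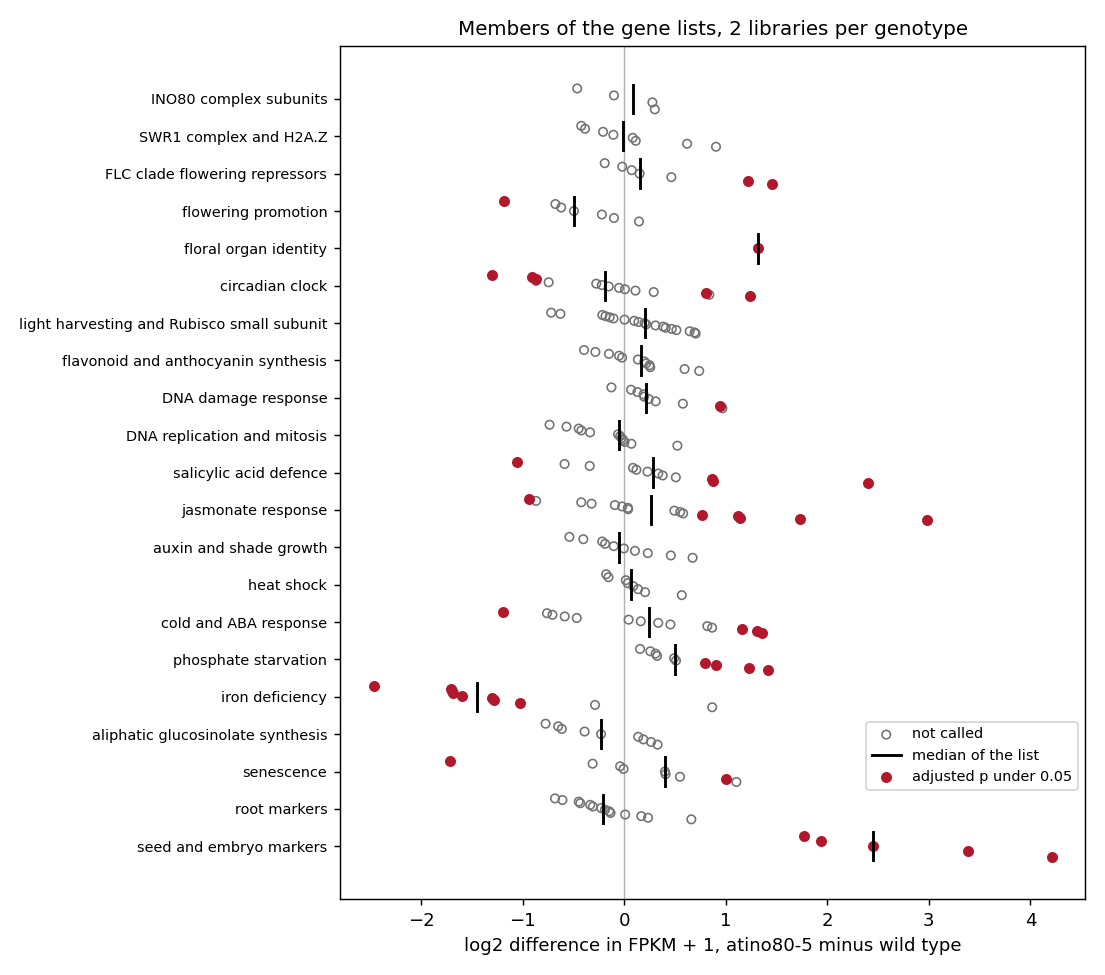
Difference in log2(FPKM + 1), atino80-5 minus wild type, for each tested member of the 21 gene lists. Filled points are members with a limma adjusted p under 0.05, open points are the others, and a black line marks the median of each list, -1.45 for iron deficiency and 2.45 for seed and embryo markers.

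In the authors' deposited table, 1945 of the 20478 genes with an adjusted p were under 0.05, 1197 of them higher and 748 lower in atino80-5. Of these, 686 were at least 2-fold higher and 514 at least 2-fold lower. The limma test on log values shared 876 of its 955 calls with that table, all 876 in the same direction, and 79 of its calls were not called there. Of the authors' calls, 1815 were among the genes tested here, and more of these were left uncalled by limma than the 876 it shared. Another 130 lay below the minimum level used here.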

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

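The tests on replicate libraries, seed composition, root markers and single mutant libraries below were chosen after the result they measure had been seen. Those on the length trend of called genes and lists were set before their own result was seen. Removal of that trend was itself added after seeing the data.

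Some genes outside the tested set had reads in only 1 genotype. Below the minimum level, 21 genes had no wild-type read and at least 3 reads in each atino80-5 library. Among them were the seed genes SESA1 (10 and 17 reads), SESA3 (3 and 5 reads) and CRU2 (5 and 6 reads) and the seed regulator gene ABI3 (12 and 7 reads). In the other direction, 74 genes had no atino80-5 read and at least 3 reads in each wild-type library, among them AGL46 (9 and 13 reads). The genes were picked for their zeros, and the number expected from counting error was not computed. In the authors' deposited table SESA1 and ABI3 had DESeq2 adjusted p-values of 0.00397 and 0.0147. SESA3, CRU2 and AGL46 had none there. The wild-type libraries were the deeper ones on the size-factor scale, 0.9995 and 1.3479 against 0.7849 and 0.9574, and a 0 in the mutant allows up to 3 reads.

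Shorter genes lay higher in atino80-5. The median log2 difference was 0.17 in the shortest of 5 equal groups of genes and -0.12 in the longest, with 236 raised and 108 lowered genes in the first and 22 and 69 in the last. Differences between the libraries of 1 genotype also followed gene length, with a Spearman rho of up to 0.294 in the wild-type pair, so a length difference between single libraries is a candidate explanation for the trend itself. The trend did not account for most of the calls: with it removed, 82.9% of the called genes were still called. The balance of calls did follow it, from 528 raised and 427 lowered to 418 raised and 458 lowered. A genotype effect on the trend stays open and untested.

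Seed storage genes were higher in both mutant libraries. RNA from seeds or embryos of 1 fixed composition would keep 1 ratio between the mutant libraries for every seed gene. The 7 genes of the seed list with at least 10 reads in atino80-5 did not, with a ratio of 2.00 for CRC and 0.433 for OLEO2. The chi-square per degree of freedom of these 7 genes was 15.0. That lay at percentile 96.5 of 10000 random sets matched on reads, where the median was 4.29. The seed genes SESA5 (144 and 149 reads) and CRU2 (5 and 6 reads) are not on the list and were not in this test. The ratios below 1 were those of OLEO2, which overlaps a neighbouring gene, and of ABI3, with 12 and 7 reads. For the 7 genes, the percentile argues only weakly against 1 fixed composition. It lies close to the bound of 95, which was set after the result had been seen. The length trend is too small to account for the rise. Group medians ran only from 0.17 to -0.12 on the log2 scale, against 2.45 for the list. With the trend removed 94.7% of the median difference remained, an outcome that so small a trend could hardly have changed. Seeds or embryos of unlike stages in the 2 mutant samples, slower loss of seed transcripts, and expression in seedling cells stay open and were not tested.

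Iron deficiency genes were lower in atino80-5. Fewer root cells would lower root markers by about as much, but their median log2 difference was -0.21 against -1.45 for the iron genes, a gap larger than the SD of 0.357 among the root markers. They went both ways, with NRT2.1 2.19-fold lower and PYK10 1.58-fold higher, and a smaller loss of root cells is not excluded. The length trend, with group medians from 0.17 to -0.12, is too small to account for the fall. With it removed 110.7% of the median difference remained, and so small a trend could hardly have removed much of it. A single odd mutant library does not either, because the median of all 10 tested iron genes kept at least 95.2% of its value with either mutant library left out. A difference in iron supply between plates, and an effect of genotype, stay open and were not tested.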

How the results depend on the processing

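Voom, removal of the length trend and scaling to total reads were chosen after seeing the data; the other alternatives were planned. DESeq2 and edgeR were planned and not run, and the authors' deposited table stands in their place as a count test. Against 955 changed genes (528 raised, 427 lowered), other pseudocounts, no filter, quantile normalisation, median centring, limma without trend, robust limma and removal of the length trend gave 876 to 1231. Besides total-read scaling, lowered genes outnumbered raised genes with no filter (445 raised, 451 lowered) and with the length trend removed (418 raised, 458 lowered). A minimum of 5 FPKM gave 572 changed and 210 lowered genes out of fewer tested. Voom gave 1614 changed, 841 raised and 773 lowered genes. Scaling to total reads gave 1633 changed and 1151 lowered genes, with raised genes at 29.5% of calls against 55.3%; the median of all genes moved to -0.157. Leaving out 1 library gave 443 to 6896 changed, 262 to 3895 raised and 181 to 3001 lowered genes. The lone library is then assumed to vary like the pair of the other genotype, and the 2 highest counts rest on the closer wild-type pair. The replicate block gave 1985 changed, 1115 raised and 870 lowered genes; replicates of the same number did not deviate together (correlation -0.034 across genes), so the numbers are not read as pairs. Camera called 4 lists, 2 with the minimum of 5 FPKM, 7 with quantile normalisation, 6 with voom, 5 each with total-read scaling and with the length trend removed, 2 to 5 without 1 library and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05; fry called 3. Where no reason is given, the cause was not tested. Iron deficiency was called under every setting except the estimated correlation, and seed markers likewise wherever 3 members were tested. The 51 called genes named by the rule, and 15 called genes named after their values were seen, kept their direction wherever measured. Of the 51, between 1 and 7 lost their call under other pseudocounts, no filter, quantile normalisation, median centring, no trend, removal of the length trend or total-read scaling, and 13 and 12 without wild type replicate 1 or 2. Of the 15, 1 or 2 lost it under no filter, removal of the length trend or total-read scaling, and 5 and 4 without wild type replicate 1 or 2. Depth limits genes near the floor of 3 reads.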

Other observations

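The family tests were chosen after seeing the data; the test around INO80 was set before its result was seen.

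Gene families, taken from the letters that start a gene symbol, were tested beside the lists. Of 109 families with at least 10 tested genes, 13 passed camera with its preset correlation. With an estimated correlation, where few degrees of freedom remain, every family had a camera adjusted p of at least 0.926. The BHLH family is among the 13 and holds iron deficiency genes described above. Of 44 UGT glycosyltransferase genes 14 fell and 1 rose (camera adjusted p = 0.00206), of 22 GSTU glutathione transferase genes 6 fell (0.00525), and of 10 ABCC transporter genes 3 fell (0.00047). The other members of these 3 families did not pass the limma test. GSTU24 went from 163.5 and 164.6 FPKM to 52.0 and 40.4 FPKM, GSTU1 from 55.2 and 53.1 to 20.7 and 17.5 FPKM, and ABCC10 had a log2 difference of -1.87. Among 21 ERF transcription factor genes 7 rose and 1 fell (0.0151), with ERF6 at 16.6 and 21.9 FPKM in wild type and 112.6 and 75.0 FPKM in atino80-5, and ERF11 with a log2 difference of 2.47. Medians of these 4 families kept their sign under quantile normalisation, median centring, total-read scaling and removal of the length trend.

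Some genes were nearly absent from 1 genotype. Of the called genes, 10 had a mean FPKM in atino80-5 of no more than 5% of that in wild type, and 14 the reverse. With a group under 3 reads set to 3 reads, a rule added after these counts were seen, 6 of the 10 and 12 of the 14 stayed under 5%, so the other genes have too few reads for that bound. Among the 6 were HDA2, a histone deacetylase gene, with 155 and 210 reads in wild type and 6 and 5 in atino80-5, and ACR1, with 166 and 249 against 4 and 5 reads. HDA2 overlaps a neighbouring gene. Of the 6, 1 had a called gene directly beside it among the tested genes, and of the 12, 1 had. These genes were picked after their values were seen.

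One hypothesis was that a stretch of other variation linked to INO80 in the mutant line changes expression of genes around it. Of the 200 tested genes nearest to INO80 on its chromosome, 11 were called, or 5.5%, against 5.41% of all tested genes. That lay at percentile 58.1 of all windows of the same size, so the hypothesis found no excess of calls around the locus. It does not exclude variation that changes few genes.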
